A study of Homo sapiens with 4 samples.

How the data were processed

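Gene expression was measured by RNA sequencing of poly(A) RNA in 4 libraries of human endometrial cancer cell lines. HEC-1-A and RL-95-2 cells had each been transfected with a mimic of tRF-20-S998LO9D, a small RNA cut from a transfer RNA, or with a negative control of the mimic. Each line gave 1 mimic library and 1 control library. The transfection and the cell line of each library were taken from the labels.

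The authors deposited raw counts per gene and FPKM values per gene, both for the same 4 libraries. Per the submitters' processing notes, CASAVA, HISAT2 and the GRCh38 (hg38) genome build were used. The counter, the annotation and the strand setting are not given in the sources used here. The table held 22494 features, of which 2963 had no count in any library, 2765 had a locus number in place of a gene symbol and 27 had a symbol turned into a date. These features stayed in library sizes and tests but were not named. Totals ranged from 33575882 to 46220053 counts per library. Gene positions, GC content and transcript length came from GENCODE release 29 (GRCh38), matched by symbol for 18931 features. The labels do not say that the libraries of a line came from separate cultures. With 1 library per line and transfection, p-values measure only the spread between these samples, where the replicates are different cell lines. The spread between cultures of a line was not measured.

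The counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, a filter on low counts by transfection, a quasi-likelihood F test and Benjamini-Hochberg adjustment at an FDR of 0.05. The model held the cell line and the transfection. The mimic and control libraries were paired by the cell line named in their labels, so the line served as a block, and 1 residual degree of freedom remained. The test therefore sets the mean response against the difference between the responses of the lines, moderated toward a spread pooled over genes. The pooled spread weighed more, with 5.44 prior degrees of freedom against the 1 residual. A gene with like responses in both lines can therefore still fail. Within a line, 1 library stood against 1, and no p-value was computed. There the log2 ratio of TMM-scaled CPM (prior count of 2) was given with an exact 95% interval from the 2 counts. Intervals and floors cover counting error only. A gene counted as apart at a ratio of at least 2-fold, with a mean of at least 1 CPM in the line. A library at 0 counts was placed at a floor of 3 counts per library for a bound on the fold.

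Gene lists of stress, signalling, cell cycle, metabolic, translation, lineage and marker genes were tested over both lines with limma 3.58.1 (camera on voom values, preset correlation of 0.01, and again with an estimated correlation). An estimated correlation rests on the 1 residual degree of freedom, which leaves that camera test little able to call a list. A call lost there cannot decide whether a list moved. The fry test was run as well. Its directional p asks whether a list moves on balance one way, and does not compare the list with other genes. Some genes belong to more than 1 list. From the integrated stress response list, ATF3 is also in the immediate early, SESN2 in the p53 and SLC7A11 in the NRF2 list. From the apoptosis list, BAX and BBC3 are also in the p53 list and BIRC5 in the mitosis list. Within a line, the median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The groups, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

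The genes named are SESN2, up to 12 genes per direction over both lines, the 8 highest and 8 lowest log2 ratios in each line at a mean of at least 5 CPM, the 2 highest and 2 lowest members of each list, and the 5 genes with the largest opposite ratios per pattern. Where no gene passed the test over both lines, the genes of lowest p-value with the same sign in both lines and a mean of at least 5 CPM over the 4 libraries took the places, and they are given as values. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that meet the rule are not reported here.

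Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, scaling by the library total, other filters and prior counts, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit with no replicate block, and each line left out. Alternatives chosen after seeing the data were a restriction to GENCODE symbols without read-through genes, removal of GC and length trends, and thinning to the smallest total. The procedure was tested on simulated data with the means and library sizes of these libraries. At the fitted spread, the edgeR test over both lines recovered 17.9% of 67 genes changed 2-fold alike in both lines, 89.4% of 66 changed 4-fold and 95.5% of 66 changed 8-fold, among 15655 genes, and called 3 unchanged genes. At a low simulated spread it recovered 97% of 67 genes changed 2-fold among 15812 and called 13 unchanged genes.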

Results

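Gene expression in HEC-1-A and RL-95-2, established human endometrial cancer cell lines, was compared between cells given a tRF-20-S998LO9D mimic and cells given a negative control of the mimic. The question was which genes differ in the presence of this tRNA-derived fragment. Total counts were 33575882 in the HEC-1-A control, 45970431 in the HEC-1-A mimic, 39999621 in the RL-95-2 control and 46220053 in the RL-95-2 mimic library. Between 17016 and 17640 features had at least 1 count. Across genes, log2(CPM + 1) of the mimic and control libraries correlated at a Pearson r of 0.997 in HEC-1-A and 0.986 in RL-95-2, and at 0.896 to 0.900 between lines. Each line had 1 library per transfection, so differences within a line have no replicate check.

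SESN2, which encodes the stress-induced protein sestrin 2 and is known to have been followed up in this study, was 5.72-fold lower in the RL-95-2 mimic library than in its control. Its level there was 165 CPM with the control and 28.8 CPM with the mimic (log2 ratio -2.52, 95% counting interval -2.60 to -2.43). In HEC-1-A, SESN2 stood at 85.4 CPM with the control and 95.3 CPM with the mimic (log2 ratio 0.16, interval 0.09 to 0.23). SESN2 lies on chromosome 1 at 28259527 to 28282491 (GRCh38). Over both lines its edgeR log2 fold change was -1.18 (SE 0.63, n = 2 per transfection, adjusted p = 0.9999), with a ratio below 0 in 1 of the 2 lines. Without RL-95-2 the log2 ratio was 0.16, and without HEC-1-A it was -2.52.

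Over both lines, interferon-stimulated genes, which encode antiviral proteins, had median log2 ratios above 0 in both lines, at 0.27 in HEC-1-A and 0.37 in RL-95-2. Of the measured members, 18 of 19 in HEC-1-A and 15 of 20 in RL-95-2 were above 0. CMPK2, a nucleotide kinase, had log2 ratios of 0.16 and 2.07, while RSAD2, an antiviral enzyme that overlaps CMPK2 on the other strand, had 0.50 and -0.85. Mitosis genes had medians of 0.13 and 0.27, with 21 of 24 members above 0 in each line. Among them, CDC20, an activator of the anaphase-promoting complex, had log2 ratios of 0.04 and 1.09, and PLK1, a mitotic kinase, 0.11 and 0.75. Cytosolic ribosomal protein genes had medians of -0.06 and -0.18, with 64 and 66 of 78 members below 0, RPL5 at -0.25 and -0.57 and RPL13A at -0.13 and -0.58. The ribosomal median in RL-95-2 lay within the random lists (percentile 15.2) and was -0.05 with scaling by library total and -0.03 on log2(FPKM + 1). With GC and length trends removed the ribosomal medians were -0.12 in HEC-1-A and -0.29 in RL-95-2. The camera test placed the interferon list higher (adjusted p = 6.2e-05), the mitosis list higher (adjusted p = 2.3e-04) and the ribosomal list lower (adjusted p = 2.7e-04). Each call was lost with an estimated correlation (adjusted p = 0.51), which cannot decide the question on 1 residual degree of freedom.

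No single gene passed over both lines. The edgeR test called 0 genes higher and 0 lower among 15957, with 167 at an unadjusted p under 0.05 (92 higher, 75 lower), where chance alone would give 798. A number this far under that of chance means that the p-values run high here. The 0 calls therefore cannot show that no gene changed in both lines. DESeq2 called 1 gene and limma-voom 0. The feature called by DESeq2 was SCHIP1-1, named after its values were seen, with 0 counts in both control libraries and 154 and 239 in the mimic libraries. Its name is the gene symbol SCHIP1 with a suffix. Its overlap with other genes was not examined, and the counts of SCHIP1 itself are not reported here. Whether reads were assigned differently between libraries was therefore not tested for SCHIP1-1, and its values are uncertain. Of the genes fixed in lists, 0 members passed when adjusted over the list alone and 0 over all genes. Among the genes of lowest p-value with the same sign in both lines and a mean of at least 5 CPM, THBS1, which encodes the matrix protein thrombospondin 1, had log2 ratios of 0.70 in HEC-1-A and 1.33 in RL-95-2. TUBA4A, an alpha-tubulin, had 0.82 and 1.08. IKBKE, a kinase of innate immune signalling, had 0.85 and 0.82, KLHDC7A 1.08 and 2.64, and DBI, an acyl-CoA binding protein, 0.64 and 1.21. KIAA1161 had 0.79 and 1.98, and KRT15, a keratin, 0.51 and 1.46. Below 0 in both lines were LCN2, an iron-handling secreted protein, at -0.83 and -1.69, BTG3 at -0.95 and -0.96, FGD4 at -0.72 and -0.88, TMEM178B at -0.59 and -1.15, GAREM1 at -0.53 and -1.27, CLGN at -0.58 and -1.93 and the kinase gene DAPK1 at -0.55 and -1.11. The edgeR adjusted p of each of these genes was 0.9999. MDGA1, TNS4, BST2, CYP1B1, CXCL1, RAB38, PTGS2 and HSD17B2 also had the same sign in both lines, but with at most 28 counts in either HEC-1-A library.

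In HEC-1-A, the mimic library held more HMOX1, the heme-degrading oxidative stress enzyme, and more ANKRD1, a target of mechanical signalling. HMOX1 was 2.55-fold higher (15.8 CPM in the control and 40.3 in the mimic library) and ANKRD1 4.78-fold higher (1.90 and 9.27 CPM). LGSN was 2.48-fold higher. Lower in the mimic library were ARHGEF18 (2.58-fold), PRICKLE2 (2.16-fold) and PPP2R2C, a phosphatase subunit (2.10-fold). In all, 113 genes were at least 2-fold higher and 31 at least 2-fold lower among 12981, which is 1.11% of genes. With a minimum of 5 CPM these numbers were 18 and 11, and on log2(FPKM + 1) the share higher was 45.8% in place of 78.5%.

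Shifts of gene lists in HEC-1-A were small. Immediate early genes, the fast transcriptional responders to growth and stress signals, had a median log2 ratio of 0.25, above all 10000 random lists, with FOSB at 0.66 and ATF3 at 0.61. Mesenchymal genes had a median of 0.38 (percentile 99.6), and NF-kB target genes 0.20 (99.5), with TNFAIP3, a feedback inhibitor of NF-kB, at 0.52. Lists of the unfolded protein response (0.16, percentile 99.9), p53 targets (0.15, 99.7), NRF2 targets (0.14, 99.8), the integrated stress response (0.14, 99.9), cholesterol synthesis (0.14, 99.3) and glycolysis and hypoxia (0.11, 97.4) also had medians above 0. CALR, an endoplasmic reticulum chaperone, had a log2 ratio of 0.41. On log2(FPKM + 1) several medians shrank, to 0.18 for mesenchymal, 0.16 for immediate early, 0.15 for interferon-stimulated, 0.08 for mitosis and 0.07 for NRF2, cholesterol synthesis and glycolysis and hypoxia genes. DNA replication genes had a median of -0.13 (percentile 0.03), with MCM5, a subunit of the replicative helicase, at -0.30. Ribosomal protein genes lay at percentile 0.02. The median of mitochondrially encoded mRNAs, -0.07 (percentile 4.96), lay within the middle 95% of random lists, and was -0.20 with GC and length trends removed. Medians were -0.05 for heat shock (percentile 11.8), 0.06 for autophagy and lysosome (80.3), -0.04 for epithelial (12.7), -0.05 for endometrial and hormone receptor (29.3) and 0.00 for tRNA synthetase genes (35.7). On log2(FPKM + 1) these 5 medians were -0.08, 0.02, -0.08, -0.02 and -0.02, and heat shock was -0.10 with GC and length trends removed. The apoptosis median of 0.02 (percentile 57.7) and the small RNA machinery median of -0.02 (percentile 26.6) turned to -0.04 and 0.02 on log2(FPKM + 1). In no list were measured members at least 2-fold lower, and 1 member each was at least 2-fold higher among interferon-stimulated, NF-kB, NRF2 and mesenchymal genes.

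In RL-95-2, genes of the integrated stress response, the program run by the transcription factor ATF4 when translation initiation is curbed, were lower in the mimic library. Their median log2 ratio was -1.42, below all 10000 random lists, and 20 of 24 members were at least 2-fold lower. ATF3, a stress-induced transcription factor, was 31.0-fold lower (129 CPM in the control and 4.12 in the mimic library). DDIT4, an inhibitor of mTOR signalling, had a log2 ratio of -3.23. ATF5 had 1.18 and was the single member at least 2-fold higher, but it overlaps NUP62 on the other strand. Overlaps of that kind also held for genes lower in the mimic library, such as FOSB and MAP1LC3B. GDF15, a stress-induced cytokine, was 27.5-fold lower (3150 and 114 CPM), and INHBE, an inhibin subunit, 53.8-fold lower (29.9 and 0.51 CPM). The camera test over both lines called the stress response list lower (adjusted p = 4.2e-10), a call lost with an estimated correlation (adjusted p = 0.51 with an estimated correlation). In HEC-1-A, 16 of 23 members were above 0, so the call rests on the RL-95-2 pair.

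**Figure D1:**
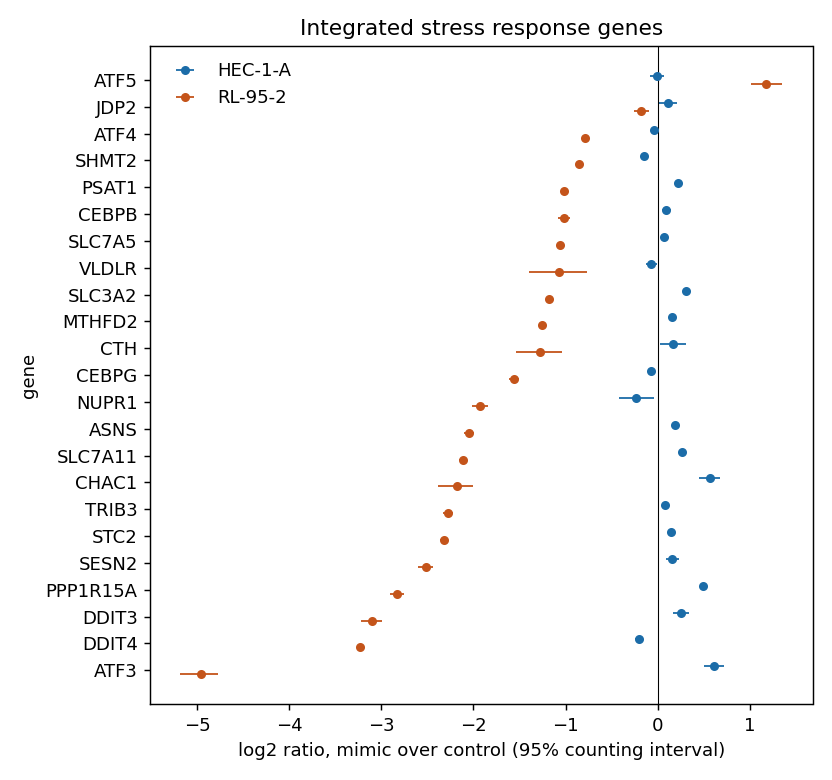
Log2 ratios of mimic over control (x axis) for 23 integrated stress response genes (y axis) in HEC-1-A and RL-95-2. Points are the ratio of 1 library to 1, and bars are 95% intervals for counting error only. PHGDH, with 0 counts in HEC-1-A, is left out. RL-95-2 values run from -4.95 for ATF3 to 1.18 for ATF5, and HEC-1-A values from -0.23 for NUPR1 to 0.61 for ATF3.

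Immediate early, NF-kB and hypoxia genes were also lower in the RL-95-2 mimic library. Immediate early genes had a median of -1.32, below all random lists, and 14 of 19 were at least 2-fold lower, among them FOSB (27.4-fold). NF-kB target genes had a median of -1.04, again below all random lists, with 9 of 18 at least 2-fold lower and the cytokine gene IL1A at -4.51, while TNFAIP3 had 0.78. PTGS2, the inducible cyclooxygenase, was 30.3-fold lower. Glycolysis and hypoxia genes had a median of -0.81 with 8 of 24 at least 2-fold lower, led by NDRG1 at -3.24, whereas the glycolytic enzyme genes TPI1 and LDHA had 0.81 and 0.66. NRF2 target genes (median -0.74, percentile 0.02) had 7 of 16 at least 2-fold lower, among them TXNRD1 at -2.07 and SLC7A11, a cystine transporter, at -2.12. For tRNA synthetase genes the median was -0.57 (percentile 0.04), with AARS at -1.78 and HARS at 0.71, and for autophagy and lysosome genes -0.38 (percentile 1.13), with MAP1LC3B at -2.61. On log2(FPKM + 1) the medians were -0.68 for NF-kB, -0.54 for glycolysis and hypoxia and -0.15 for autophagy and lysosome genes, the last -0.25 with scaling by library total. The camera calls over both lines for these lists were lower, with adjusted p of 1.2e-05 for immediate early, 2.8e-04 for NF-kB, 1.2e-03 for glycolysis and hypoxia, 2.7e-03 for tRNA synthetase and 0.047 for both NRF2 and autophagy genes, and none held with an estimated correlation (adjusted p = 0.51). The NF-kB call was also lost with at least 1 CPM in all 4 libraries (adjusted p = 0.54) and with no block for the line (adjusted p = 0.074), and the NRF2 and autophagy calls with RLE size factors (adjusted p = 0.052 for both). In HEC-1-A, 15 of 20 immediate early, 11 of 12 NF-kB, 15 of 23 glycolysis and hypoxia and 12 of 18 NRF2 members were above 0. The same held for 15 of 17 autophagy and lysosome and 10 of 20 tRNA synthetase members, so these calls rest on the RL-95-2 pair.

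Heat shock and DNA replication genes were higher in the RL-95-2 mimic library. HSPA8, the constitutive HSP70 chaperone, was 12.6-fold higher (136 CPM in the control and 1719 in the mimic library), and HSP90AA1 had a log2 ratio of 1.99. HSPA1A was 5.26-fold higher, although its reads cannot be told apart from those of the near-identical HSPA1B. The heat shock median was 0.98 (percentile 100) with 7 of 14 at least 2-fold higher, while BAG3 and DNAJB1 had -0.22 and -0.13. DNA replication genes had a median of 0.87 (percentile 100), with 6 of 20 at least 2-fold higher and 19 of 20 above 0, among them MCM5 at 1.58 and UHRF1 at 1.29. The epithelial keratin genes KRT13 and KRT5 were 5.74-fold and 5.70-fold higher, and ALPP, a placental alkaline phosphatase, 5.44-fold. The camera calls, made over both lines, were higher for heat shock (adjusted p = 3.0e-04) and DNA replication genes (adjusted p = 6.2e-05). Neither held with an estimated correlation (adjusted p = 0.51). In HEC-1-A, 9 of 14 heat shock and 17 of 20 DNA replication members were below 0, so the calls rest on the RL-95-2 pair.

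The medians of other lists in RL-95-2 lay nearer to those of the random lists, although single members moved. Among 26 p53 targets, 4 were at least 2-fold higher and 6 lower. At least 2-fold lower were 5 of 22 apoptosis genes and 4 of 18 unfolded protein response genes, with 0 higher in either list. The unfolded protein response median was -0.16 (percentile 26.2), with XBP1 at -1.66 and CALR at 0.66. Apoptosis genes had -0.22 (4.99), mesenchymal genes -0.34 (4.44), epithelial genes -0.25 (12.1), cholesterol synthesis genes 0.13 (84.6) and mitochondrially encoded mRNAs 0.15 (95.1). On log2(FPKM + 1) medians were -0.02 for the unfolded protein response and apoptosis, -0.16 for epithelial genes, 0.28 for cholesterol synthesis genes and 0.29 for mitochondrially encoded mRNAs, the last 0.04 with GC and length trends removed. The p53 target median of -0.08 (percentile 24.7) turned to 0.05 when scaled by library total and 0.03 on log2(FPKM + 1), with GDF15 and TP53I3, at 1.31, on opposite sides. Medians of small RNA machinery genes (-0.18, percentile 17.7) turned to 0.04 on log2(FPKM + 1), and those of endometrial and hormone receptor genes (0.03, percentile 50.6) to -0.09 with GC and length trends removed. Of 14 blood and immune cell markers, 0 were measured in HEC-1-A and 1 in RL-95-2. Of 10 endothelial markers, 1 and 4 were measured, with ERG at 1.15 and CDH5 at 0.80 in RL-95-2. Over both lines, camera called the list higher on 5 genes (adjusted p = 0.027). The camera call was lost with an estimated correlation (adjusted p = 0.51) and with no block for the line (adjusted p = 0.48). Across RL-95-2, 619 genes were at least 2-fold higher and 857 lower among 13151, which is 11.2% of genes. The share higher was 41.9%, against 56.1% with scaling by library total and 55.6% on log2(FPKM + 0.1), settings that moved the median of all genes to 0.13.

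**Figure D2:**
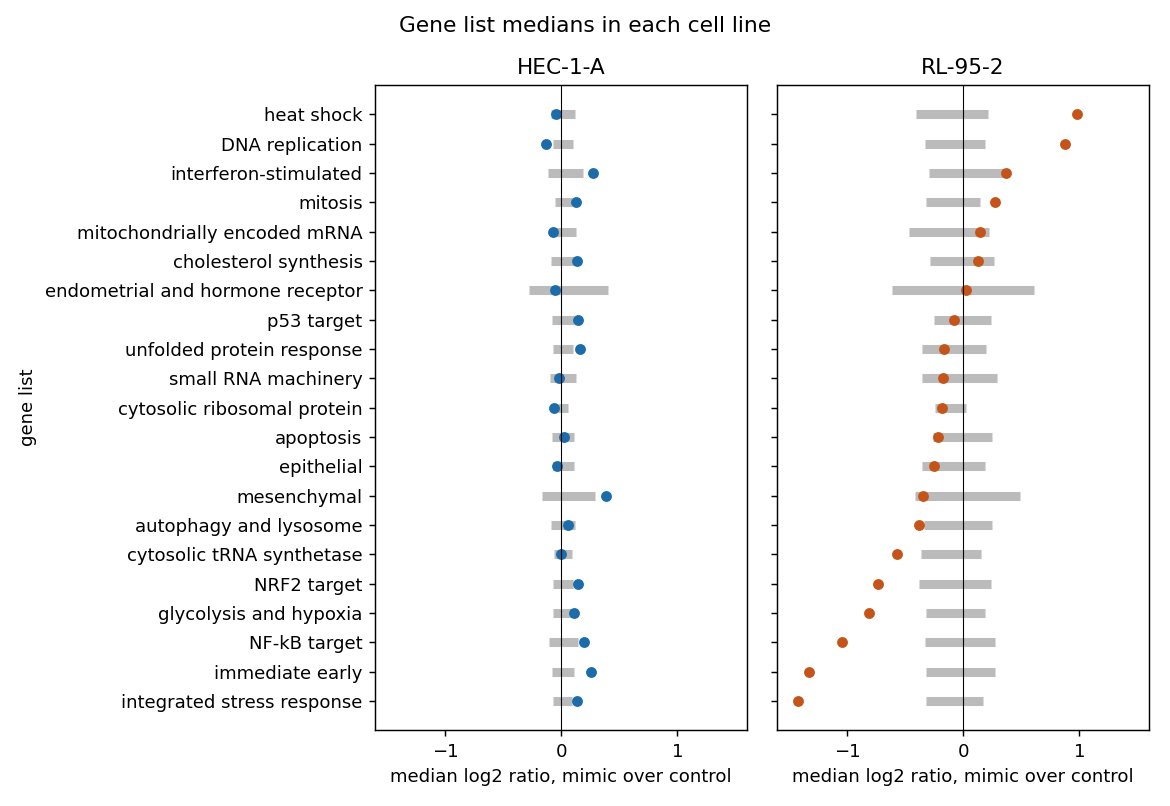
Median log2 ratio of mimic over control (x axis) of 21 gene lists (y axis) in HEC-1-A and RL-95-2, 1 library against 1. Grey bars span the middle 95% of 10000 random lists of the same size matched on mean expression. RL-95-2 medians run from -1.42 for the integrated stress response to 0.98 for heat shock, and HEC-1-A medians from -0.13 to 0.38. The signs of the p53, endometrial and small RNA machinery medians in RL-95-2, and of the apoptosis and small RNA machinery medians in HEC-1-A, flip under other scalings or corrections.

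Between the lines, the same genes had largely different ratios. HMOX1 was higher in the HEC-1-A mimic library and 5.55-fold lower in that of RL-95-2. CYP1A1, a target of the aryl hydrocarbon receptor, was 2.88-fold higher in HEC-1-A (2.14 and 6.25 CPM) and 14.1-fold lower in RL-95-2 (825 and 58.4 CPM). TRPV3, an ion channel gene, and TMEM40 had log2 ratios of 2.04 and 1.44 in HEC-1-A and -1.38 and -1.42 in RL-95-2. TP73, a p53 family member, had -1.77 and 1.76. Among heat shock genes, HSPA8 had -0.92 and 3.66, and HSPA1A had -0.86 and 2.40. TRPV3, TMEM40 and TP73 had a mean under 1 CPM in HEC-1-A. CXCL2 and SLC2A3 were lower in RL-95-2 (log2 ratios -2.65 and -1.79), and in HEC-1-A they had 0 counts with the control and 8 and 6 with the mimic, too few to set a direction for SLC2A3 (lower end of its counting interval -0.20). Across 11913 genes with a mean of at least 1 CPM in both lines, the log2 ratios correlated at a Pearson r of -0.127 and a Spearman rho of -0.148, although genes are not independent replicates. Among genes at least 2-fold apart, 6 were higher in both lines (2.23 from independent lists) and 3 lower in both (1.45), while 16 were higher in HEC-1-A and lower in RL-95-2 (3.35) and 7 the other way (0.961). Among GENCODE symbols without read-through genes, 3 were higher in both lines, 1 lower in both, 12 higher in HEC-1-A and lower in RL-95-2 and 3 the other way.

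**Figure D3:**
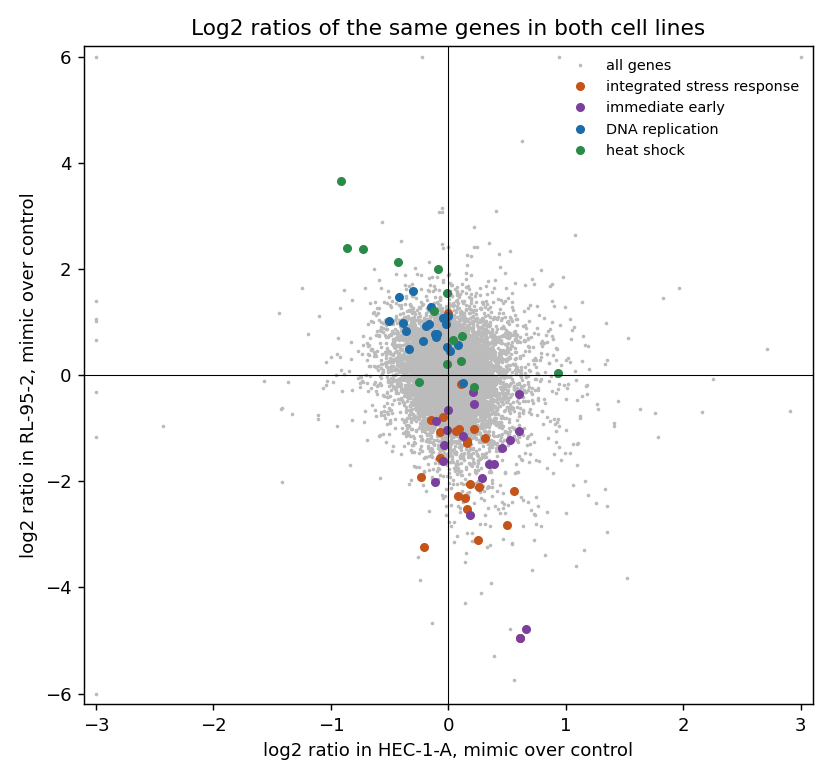
Log2 ratio of mimic over control in HEC-1-A (x axis) and RL-95-2 (y axis) for 11913 genes, with members of 4 gene lists in colour. Each value is 1 library against 1, and 11 genes beyond the axis limits are drawn at the edge. Values spread more widely along the RL-95-2 axis, with a Pearson r of -0.127 across genes.

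Several of the largest ratios belonged to read-through genes, to features that overlap other genes or have near-identical copies, and to features with no position matched in GENCODE. In HEC-1-A, the read-through gene BIVM-ERCC5 had 1434 counts in the control and 0 in the mimic library, at least 646-fold lower, while its member ERCC5 was 2.40-fold higher. JMJD7-PLA2G4B was at least 151-fold lower in HEC-1-A and at least 289-fold higher in RL-95-2, and PPAN-P2RY11 was at least 97.7-fold and at least 168-fold lower. RPL36A-HNRNPH2 had log2 ratios of -3.80 and 1.02, and RPL17-C18orf32 of 1.34 and 0.97. CTD-2207O23.3 had 0 and 1025 counts in HEC-1-A (at least 253-fold higher), and XXbac-BPG32J3.22 had 0 and 853 in RL-95-2 (at least 225-fold higher). These 2 features had no matched position, so their overlap with other genes was not examined. BEST1, 39.1-fold lower in RL-95-2, overlaps the ferritin gene FTH1 on the other strand. Genes named above that also overlap another on the other strand include FOSB, MAP1LC3B, HSP90AA1, CYP1B1, TUBA4A, GAREM1, TP73, TPI1, HARS, DNAJB1 and RPL5. AL513122.1 overlaps GSN, while BOLA2 and FAM156B have near-identical copies, so the values of read-through, overlapping and copied genes are uncertain.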

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

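The test of exchanged labels was chosen after the result was seen, as were the thinning, the GC and length correction and the restriction to GENCODE symbols. The limit to more than 3 counts in each library, used below for single genes on opposite sides, was chosen then as well. Differences between the lines were not tested, since each line has 1 library per transfection. SESN2 and several lists lay on opposite sides of 0 in the lines. The HEC-1-A value minus the RL-95-2 value was 2.67 for the log2 ratio of SESN2, and for list medians 1.56 in the integrated stress response, 1.58 in immediate early genes, 1.24 in NF-kB target genes, 0.88 in NRF2 target genes and -1.002 in DNA replication genes. Among single named genes with more than 3 counts in each library, those with ratios of at least 2-fold on opposite sides were CYP1A1 (5.34), HMOX1 (3.82), TRPV3 (3.42), RP11-385D13.1 (2.96), TMEM40 (2.86), TP73 (-3.52) and RPL36A-HNRNPH2 (-4.81). Of these, TRPV3, TMEM40 and TP73 had a mean under 1 CPM in HEC-1-A. The limit left out named genes with 0 counts in a library, such as JMJD7-PLA2G4B, BIVM-ERCC5 and CXCL2.

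RL-95-2 had more genes at least 2-fold apart than HEC-1-A, 1476 against 144. The size of the gap depends on the setting, with 2463 against 839 at a minimum of 0.1 CPM, 941 against 29 at 5 CPM and 722 against 24 on log2(FPKM + 1). Depth is argued against, since the RL-95-2 number was 10.1 times the HEC-1-A number after thinning all libraries to the smallest total. Trends with GC content or transcript length are argued against by a ratio of 11.0 after their removal. A ratio of 12.4 among GENCODE symbols without read-through genes argues against read-through genes themselves as the source. Genes that overlap another gene stayed in that set, so reads shared between overlapping genes in general were not tested. A different response of the lines, a different uptake of the mimic and a difference between cultures may each account for it, all untested.

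Lower integrated stress response genes in the RL-95-2 mimic library were weighed next. A GC or length trend is argued against, since the list median stayed at -1.42 with both trends removed. HEC-1-A RNA mixed into the RL-95-2 mimic library is argued against, since 25 genes found in HEC-1-A alone reached a median of 0% of their HEC-1-A level there (highest 0.707%). Exchanged mimic and control labels in RL-95-2 cannot be told apart from an opposite response, since the list medians of the lines correlated at a Spearman rho of -0.39 across lists and the mimic itself was not measured. A biological response to the fragment, untested, and a stressed RL-95-2 control culture, examined only for glucose shortage and not decided, stay open.

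Read-through genes, transcripts that join neighbouring genes, were among the largest log2 ratios in both lines, with 25.8% of those measured in HEC-1-A and 24.1% in RL-95-2 at least 2-fold apart. A candidate explanation is that reads shared with the member genes were assigned differently between libraries. In the 15 cases at least 2-fold apart, the median absolute log2 ratio was 5.52 alone and 0.13 after the counts of the member genes were added, and 0 stayed at least 2-fold apart. Where the members hold more counts, the sum moves toward their own ratio whether or not reads were reassigned. The fall therefore cannot decide whether reads were assigned differently. No biological explanation was tested for these genes.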

How the results depend on the processing

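The mimic and control libraries were paired by cell line, and without the replicate block edgeR still called 0 genes higher and 0 lower (5 at an unadjusted p under 0.05), SESN2 had a log2 fold change of -1.01 and camera called 11 lists in place of 13. The calls lost without the block were NF-kB (adjusted p = 0.074) and endothelial genes (adjusted p = 0.48), and no other call changed. RLE size factors lost the NRF2 and autophagy calls (adjusted p = 0.052 for both), and a minimum of 1 CPM in all 4 libraries lost NF-kB (adjusted p = 0.54) and left the endothelial list without a value. DESeq2 called 1 gene higher, limma on log2(FPKM + 0.1) called 1 higher and 1 lower (SCHIP1-1 and PPAN-P2RY11), and limma-voom, RLE size factors, no filter, a stricter filter, log2(FPKM + 1) and GENCODE symbols alone gave 0. Of the 13 lists called by camera, 0 were called with an estimated correlation and 0 by fry, where the smallest adjusted p was 0.069 for ribosomal protein genes. The estimated correlation rests on 1 residual degree of freedom, and the lowest unadjusted camera p with it was 0.10. Calls lost there therefore cannot decide whether a list moved. Leaving out 1 line left no residual degrees of freedom, so it gave values with no test, and for SESN2 they ran from -2.52 to 0.16, of opposite sign to the joint value when RL-95-2 was left out. The 113 genes at least 2-fold higher in HEC-1-A became 18 at a minimum of 5 CPM, 576 at 0.1 CPM, 11 on log2(FPKM + 1) and 46 on log2(FPKM + 0.1), and the 31 lower became 11, 263, 13 and 21. In RL-95-2 the 619 higher became 336, 1196 and 351 at 5 CPM, 0.1 CPM and log2(FPKM + 1), and the 857 lower became 605 and 1267 at 5 and 0.1 CPM, 371 on log2(FPKM + 1) and 507 on log2(FPKM + 0.1). The filters act through the number of weakly expressed genes, and for FPKM the cause was not tested. The correlation of the lines was -0.198 at 5 CPM, -0.182 at 20 CPM, -0.160 on log2(FPKM + 1) and -0.148 as Spearman rho, against -0.127. The other genes named over both lines kept their sign under each setting run, which for a line left out follows from the rule that chose them. On log2(FPKM + 1), the medians of 14 of 21 lists in HEC-1-A and 11 of 22 in RL-95-2 moved by over 1.5 times or changed sign, against 4 and 10 with scaling by library total, 6 and 4 with GC and length trends removed and 1 and 1 with RLE size factors. Depth limits genes with few counts, where counting intervals are wide.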

Other observations

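The test in this part was chosen after the values were seen. The cytochrome P450 genes CYP1A1 and CYP1B1 were lower in the RL-95-2 mimic library, with log2 ratios of -3.82 and -2.25 (CYP1B1 at 275 CPM in the control and 58.0 in the mimic library). TXNIP, an arrestin-family inhibitor of thioredoxin that responds to glucose, was 7.57-fold lower there (789 and 104 CPM) and had 0 counts in both HEC-1-A libraries. HSPA5, the main chaperone of the endoplasmic reticulum, had -1.40 in RL-95-2 and 0.15 in HEC-1-A. TXNIP, ARRDC4 and HSPA5 lie outside the naming rule and were chosen after their values were seen.

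A hypothesis for the higher integrated stress response genes in the RL-95-2 control was that its culture ran short of glucose, which could raise stress genes. TXNIP and ARRDC4, transcripts that drop when glucose is short, would then be lower in the control. Both were higher in the control, with log2 ratios of mimic over control of -2.92 (counting interval -2.96 to -2.88) and -1.23 (interval -1.33 to -1.13), against the hypothesis. HSPA5, a chaperone gene induced when glucose is short, was 2.64-fold higher in the control, as the hypothesis needs. The values go both ways and were known when the test was set, so glucose shortage stays open. Shortage of amino acids, crowding and a response to the mimic were not tested.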
